A study of Homo sapiens with 6 samples.

How the data were processed

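Total RNA from 3 populations of the human breast cancer cell line MDA-MB-231, the parental line and the isolates S1a and S1b, was labelled with biotin and measured on 6 Affymetrix expression arrays, 2 per population. The deposited values were intensities on a linear scale, 1 signal per probe set and array, made with MAS5 per the submitters' processing notes (version not given in the sources used here). From the values themselves, none was below 0, and every array had the same mean signal of 500.2 after the highest and lowest 2% were trimmed. The deposited intensity values were used with that scaling, and their medians differed between arrays. Scanner files and detection calls were not used here, so background correction could not be repeated and a probe set could not be called absent. Arrays have no read depth; their number, 2 per population, limits the precision.

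The table held 22277 probe sets. The 62 Affymetrix control probe sets were left out of the tests, which left 22215. A probe annotation table gave 1 gene symbol for 19064 of these, several for 1043 and none for 2108, and probe sets of the latter kinds were neither tested nor named. Symbols were updated through gene identifiers in a RefSeq gene table (assembly GRCh38.p14), which matched 19052 probe sets, and that table was also used for which genes neighbour each other. The named probe sets covered 11963 genes, 4310 of them with more than 1 probe set. The value of a gene was that of its probe set with the highest mean over the 6 arrays.

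Signals were analysed as log2(signal + 3.942), where the pseudocount was the 10th percentile of all signals, so fold changes are on that scale and understate the change of dim genes. Probe sets whose mean over the 6 arrays lay below the 40th percentile (44 signal units) were left out, and 7791 genes were tested. Where the dimmer side of a comparison lay below 44 units, the ratio of the brighter mean to 44 is given as a lower bound ("at least N-fold"), because the fitted change then depends on the pseudocount.

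A model with the 3 group means was fitted to all 6 arrays with limma 3.58.1 in R 4.3.3, with moderated variances that follow the mean signal (7 prior and 3 residual degrees of freedom). All groups shared 1 estimate of the spread. The contrasts were S1a minus parental, S1b minus parental, the mean of both isolates minus parental, and S1b minus S1a, with Benjamini-Hochberg adjustment over the genes within each contrast and a threshold of 0.05. Adjusted p-values of single genes are limma's throughout. Data with no effect were simulated for all 6 arrays (100 data sets), with both isolates set against the same simulated parental arrays. They gave the overlap and correlation to expect from shared controls if all groups had the same spread.

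Before the data were examined, 36 gene lists with 981 entries were fixed, of which 108 entries had no named probe set. Lists with at least 5 tested members, 31 in all, were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists. camera with an estimated correlation and fry were run beside it. With an estimated correlation camera tests on the 3 residual degrees of freedom, so few lists could pass. A call that ends there does not by itself show that correlated genes produced it. The lists overlap, so their tests are not independent of each other. For each list, the number of members past the threshold is given over all genes tested and adjusted over the list alone.

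The genes named in the text were set by a rule that was fixed together with the lists. For the mean of both isolates against parental and for S1b against S1a, it took the 10 largest rises and the 10 largest falls among genes past the threshold whose arrays did not overlap between the sides, and up to 4 members of each described list with the smallest p-values. MMP1, FSCN1, CXCL1, IL6 and CXCL8 were always named, because published work on these populations followed them up; they may have been chosen from these arrays, so their values are not independent evidence. A gene whose other probe sets gave the opposite sign is said to disagree. For some such genes, a change under the mean of their probe sets or without shared-probe suffixes is given instead. Of the genes taken by this rule, 1 is not reported here.

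The procedure was tested on simulated data with the means and spread of the 7791 genes and 200 changed genes in each of 20 runs. For the mean of both isolates against parental, 64.3% of 1.5-fold, 85.7% of 2-fold and 94.2% of 4-fold changes were recovered, with 6.96% false calls. For S1b against S1a, the shares were 54.5%, 81.5% and 95.3%, with 7.1% false calls. For S1a against parental they were 57.1%, 80.4% and 95.5%, with 5.42% false calls. All these false shares lay above the threshold of 0.05. The simulated noise was independent and the same in all groups, and far fewer genes changed than the 3600 called against parental. These shares therefore describe the simulated data and may not hold for the real arrays.

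Alternatives fixed beforehand varied the pseudocount, the filter, the scaling (median centring, quantile and cyclic loess normalization), the variance model, array weights, the choice of probe set, the arrays in the fit and a replicate block, and left out each array in turn. One more, separate parental arrays for S1a and S1b, was added after the data were seen; each parental array was then its own group and was assumed to vary like the isolate arrays. The labels give the same replicate numbers in each population but name no shared culture, batch or day, so the numbers were not taken to pair the arrays. The sources used here give no processing batch either. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.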

Results

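Expression profiles were obtained for the parental MDA-MB-231 line and for its isolates S1a and S1b, with 2 arrays for each of the 3 populations. MDA-MB-231 is a human triple-negative breast cancer line with mesenchymal traits that is widely used to study metastasis. S1a and S1b are labelled as separately isolated populations of seeder cells, that is, tumour cells able to return from the circulation to an existing tumour. All cells were grown subconfluent in medium with 10% serum. The comparison with the parental line asks which genes distinguish these isolates from it, and the comparison of S1b with S1a asks how far the isolates resemble each other. No isolated population of cells other than seeder cells was measured. A change tied to seeding therefore cannot be told apart from any other effect of isolation. The titles call the arrays of a population biological replicates without naming separate cultures, so p-values measure the spread between these arrays. They do not measure the spread between separately isolated populations.

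Every array had a trimmed mean signal of 500.2, and median signals ran from 87.6 to 106 units. The log2 signals of the 2 arrays of a population correlated across genes with r = 0.9778 for parental, 0.9871 for S1a and 0.9854 for S1b. Between S1a and S1b arrays r lay between 0.9788 and 0.9805, and between isolate and parental arrays between 0.9197 and 0.9321. Genes are not independent replicates, so these coefficients describe the arrays only. The first principal component held 68.3% of the variance and parted both parental arrays (-42.2 and -41.6) from the 4 isolate arrays (17.6 to 24.6). The next one held 11.1% and parted S1a (-15.2 and -14.4) from S1b (13 and 14.1). Poly-A spike-in transcripts, which are added before labelling, had a mean log2 signal of 7.45 and 8.25 on the parental arrays, 8.66 and 8.57 on the S1a arrays and 8.14 and 8.07 on the S1b arrays. The ratio of the 3' to the 5' probe set of GAPDH was 1.06 and 1.09 on the parental arrays and between 0.976 and 0.998 on the isolate arrays.

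MMP1 and ADAMTS1 were among the largest rises in the isolates against the parental line, and RARRES2 and TNFSF10 among the largest falls. Taken as the mean of both isolates, the collagenase MMP1 rose by 4.61 ± 0.077 (log2, SE, 4 isolate against 2 parental arrays, limma adjusted p = 3.13e-10), from a signal of 363 ± 34.7 (SD, n = 2) to 6600 ± 93.5 in S1a and 12100 ± 153 in S1b. The secreted metalloproteinase ADAMTS1 rose by 4.63 ± 0.11, from 54.6 to 1460 units. The survival gene BCL2A1, a BCL2 family member, rose at least 12.3-fold. IL13RA2, a decoy receptor for interleukin 13, rose at least 11-fold in the mean of both isolates, from 6.65 units to 892 in S1a but only 75 in S1b. PLCB1, a phospholipase C, rose at least 11-fold, the Slit receptor ROBO1 at least 13.7-fold, the teneurin TENM3 at least 6.67-fold and amphiphysin (AMPH) at least 6.19-fold. The PLCB1 change went from 5.16 to 2.79 with the mean of its probe sets and kept its call. KHDRBS3, which encodes an RNA-binding protein, rose by 4.26 ± 0.22, from 69.2 to 1330 units.

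Among the falls, RARRES2, which encodes the chemoattractant chemerin, went from 764 ± 109 units to 4.82 ± 2.31 in S1a and 5.99 ± 1.48 in S1b, a fall of at least 17.4-fold (limma adjusted p = 3.2e-06). TNFSF10, the death ligand TRAIL, fell at least 17.6-fold, from 773 to 20.7 units. CEMIP, a hyaluronan-binding protein, fell by 4.88 ± 0.22 on the log2 scale and FLG (filaggrin) at least 11.5-fold. The antiviral gene RSAD2 fell at least 5.01-fold, CLIC3 at least 5.99-fold, MFHAS1 at least 6.83-fold, the ubiquitin ligase RNF144A at least 3.21-fold, the organic anion transporter SLCO3A1 at least 3.66-fold and HCP5, a noncoding gene of the major histocompatibility complex, at least 3.63-fold. By the rule that chose the genes given in these rises and falls, all 4 isolate arrays lay on the same side of both parental arrays. Each of these genes stayed past the threshold under every alternative that gave it a value and with each array left out.

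Of 7791 genes tested, 3600 (46.2%) passed the threshold in the mean of both isolates against parental with limma, 1771 higher and 1829 lower. Of these, 714 changed at least 2-fold (249 higher, 465 lower) and 176 at least 4-fold (63 higher, 113 lower). Most of the called changes were small, with a median size of 0.58 on the log2 scale. With probe sets of shared-probe suffixes left out, 2056 genes passed among 4771 tested, and with all probe sets 5598 passed. With array weights, which let the spread differ between arrays, 3206 passed.

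**Figure D1:**
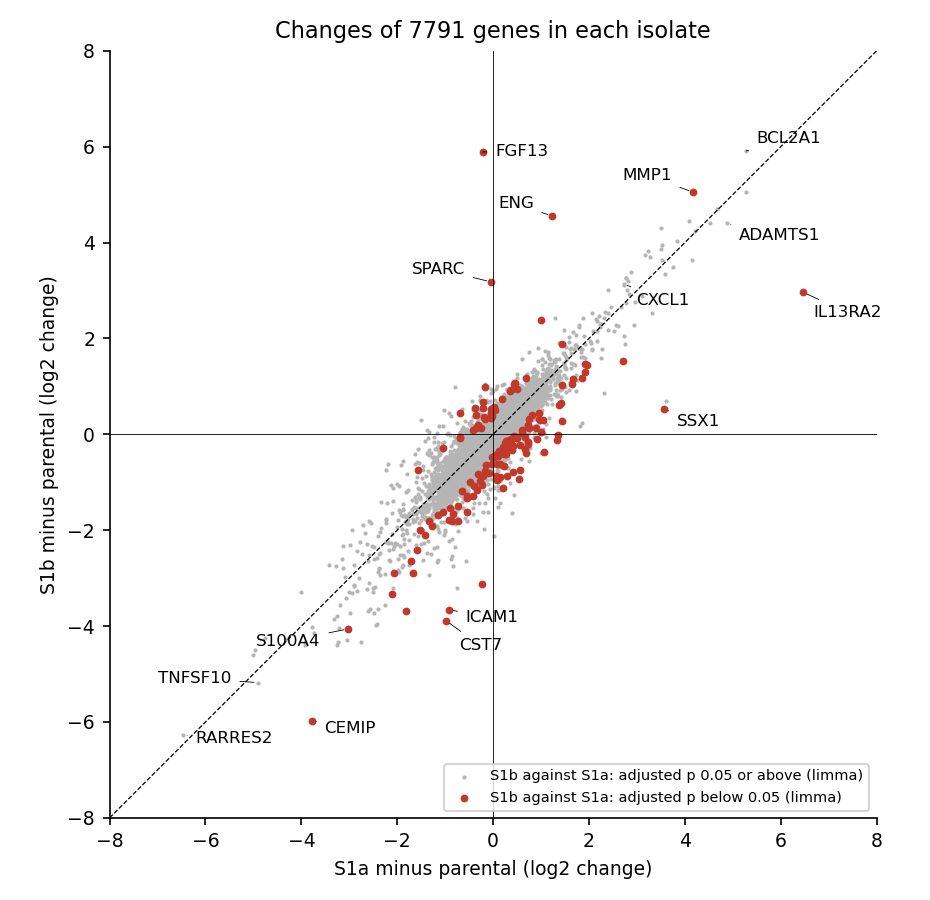
Log2 change against the parental line in S1a (horizontal axis) and S1b (vertical axis) for the 7791 genes tested; each point is a gene, red points are the 147 genes past the threshold between S1b and S1a, and the dashed line marks equal change. MMP1, BCL2A1 and ADAMTS1 lie high and TNFSF10 and RARRES2 low in both isolates, while FGF13, ENG and SPARC lie high in S1b.

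Of the genes followed up in published work, 4 were higher in the isolates and 1 was lower. Beside MMP1, the neutrophil-attracting chemokine CXCL1 rose by 2.93 ± 0.12 (log2, SE, limma adjusted p = 1.46e-07), from 94.9 ± 13.7 units to 645 ± 40.2 in S1a and 861 ± 6.95 in S1b (SD, n = 2). CXCL8, which encodes interleukin 8, rose by 1.69 ± 0.084 (adjusted p = 3.84e-07), from 514 to 1690 units. The actin-bundling gene FSCN1 rose by 1.24 ± 0.31 (adjusted p = 0.00793), and its dimmer probe set gave 2.42. IL6, which encodes interleukin 6, fell by 2.34 ± 0.29 on the log2 scale (adjusted p = 0.000142), from 621 ± 79.2 units to 163 ± 16.6 in S1a and 96.5 ± 58.8 in S1b. The call of FSCN1 ended without parental replicate 1, at a value of 0.69, and without the variance trend (limma adjusted p = 0.0563). Its value was 2.91 without parental replicate 2 and 2.37 without S1a replicate 2. Both came from its dimmer probe set, which had the higher mean once that array was left out.

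**Figure D2:**
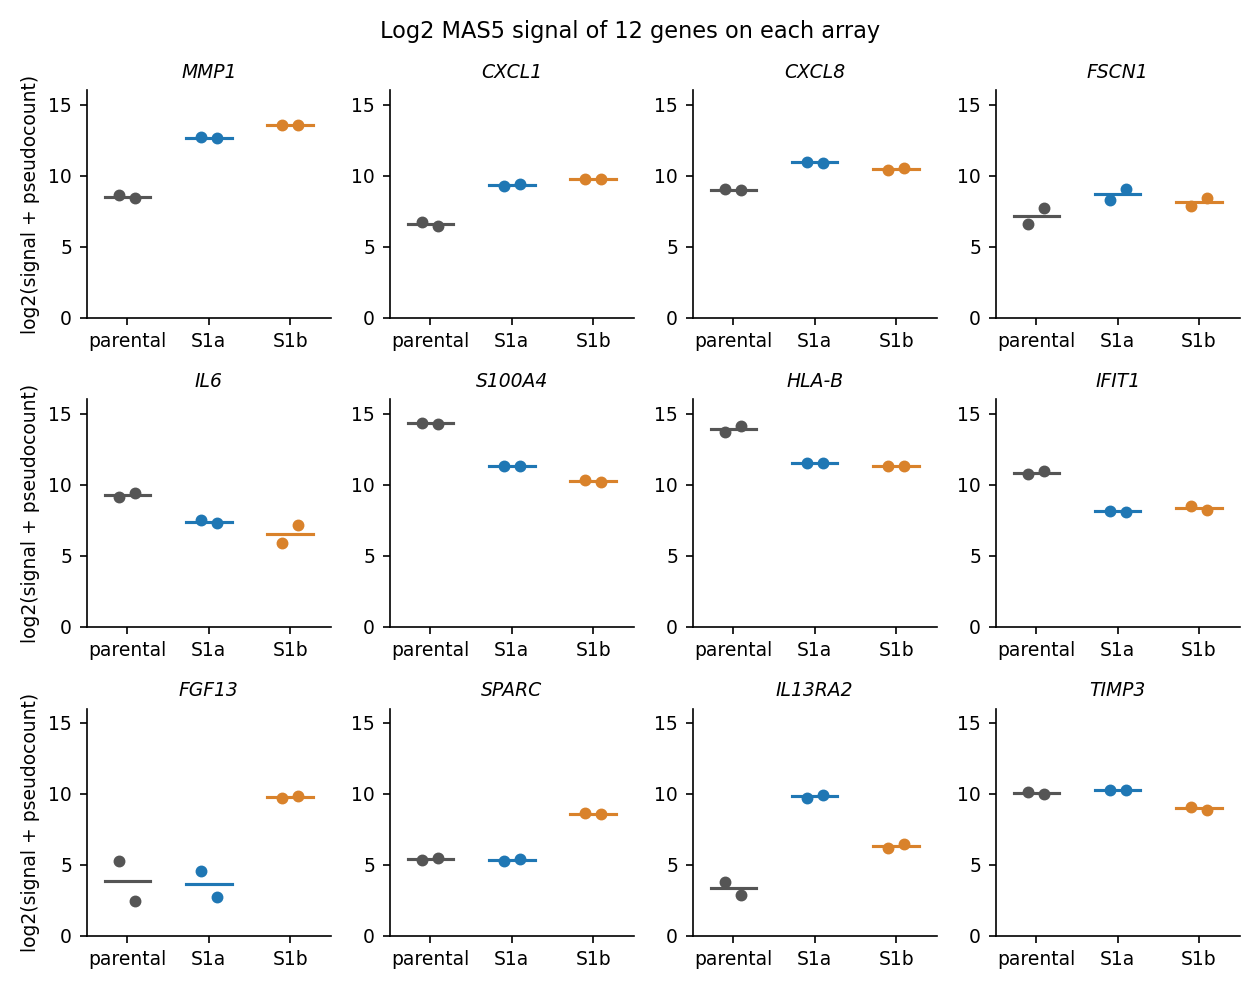
Log2 of the MAS5 signal plus the pseudocount (vertical axis) on each array for 12 named genes in the parental line, S1a and S1b; points are arrays and horizontal lines are the means of 2 arrays. MMP1, CXCL1 and CXCL8 are higher and IL6, S100A4, HLA-B and IFIT1 lower on all 4 isolate arrays, and FGF13 and SPARC are high on the S1b arrays alone.

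Among genes reported high in metastatic derivatives of this line, those of bone-metastatic derivatives rose most uniformly. Of 10 tested genes of the bone-metastatic derivatives, 9 rose and none fell (9 rose adjusted over the list alone, median log2 change 1.54, camera adjusted p = 1.66e-08), among them MMP1, ADAMTS1, the matricellular factor CCN2 (1.58 ± 0.076) and the proteoglycan SRGN (1.41 ± 0.07). Of 12 genes of brain-metastatic derivatives, 7 rose and 1 fell (7 and 1 adjusted over the list alone, median 1, camera adjusted p = 0.000898), with MMP1, the collagen COL13A1 (1.15 ± 0.07), the lysyl hydroxylase PLOD2 (1.07 ± 0.094) and the growth factor HBEGF (0.93 ± 0.082) leading. With an estimated correlation, neither call held (camera adjusted p = 0.199 for bone and 0.236 for brain). That correlation was 0.0472 for bone, above the preset 0.01, but -0.017 for brain, below it. For brain, a higher correlation was thus not why the call ended. For bone, the higher correlation and the test on 3 degrees of freedom were not told apart. Of 15 genes of lung-metastatic derivatives, 7 rose and 4 fell (7 and 4 adjusted over the list alone, median 0.66), and the list did not pass (camera adjusted p = 0.0732). MMP1, CXCL1 and IL13RA2 rose in it, and the adhesion scaffold NEDD9 fell by 2.64 ± 0.21 on the log2 scale. The 3 tested genes reported low in metastatic derivatives all fell (3 adjusted over the list alone), TNFSF10 as given above, PLAAT4 with a log2 change of -3.53 ± 0.21 and LY6E of -2.4 ± 0.15, a list too short for camera. MMP1 belongs to the bone, brain and lung lists, FSCN1 to the brain and lung lists and CXCL1 to the lung list, so these lists share members.

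Antigen presentation and interferon-stimulated genes were lower in the isolates. Of 26 antigen presentation genes, none rose and 22 fell (22 adjusted over the list alone, median -1.18, camera adjusted p = 2.48e-11, adjusted p = 0.236 with an estimated correlation). The class I heavy chain HLA-B fell by 2.5 ± 0.098 on the log2 scale, from 15700 ± 2840 units to 2890 ± 9.57 in S1a and 2610 ± 2.31 in S1b. HLA-C (-2.23 ± 0.088), HLA-G (-2.24 ± 0.092) and HLA-F (-2.15 ± 0.1) fell as well. Probe sets of these 4 genes share probes with related genes, so the share of each gene in the change is uncertain. Of 37 interferon-stimulated genes, 2 rose and 23 fell (2 and 24 adjusted over the list alone, median -0.77, camera adjusted p = 1.03e-06, adjusted p = 0.199 with an estimated correlation). The antiviral genes IFIT1, IFI27 and BST2 fell, with log2 changes of -2.61 ± 0.11, -2.85 ± 0.13 and -3.04 ± 0.15, and so did ISG15, a ubiquitin-like modifier (-1.34 ± 0.076). The spike-in signals given above also differed between isolate and parental arrays, by 0.51 on the log2 scale, beside 0.8 between the parental arrays.

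Several epithelial, luminal and mesenchymal markers fell as well. Of 15 epithelial markers, 7 fell and none rose (7 adjusted over the list alone, median -0.33, camera adjusted p = 0.0183, adjusted p = 0.487 with an estimated correlation), including the keratins KRT7 (-2.59 ± 0.097) and KRT8 (-1.58 ± 0.086), desmoplakin (DSP, -2.23 ± 0.11) and the mucin MUC1 (at least 6.76-fold lower; its log2 change went from -2.91 to -1.68 with the mean of its probe sets and kept its call). Of 12 luminal markers, 8 fell and none rose (8 adjusted over the list alone, median -0.59, camera adjusted p = 0.0183, adjusted p = 0.487 with an estimated correlation), including the transcription factor GATA3 (-1.55 ± 0.13) and AGR2 (-1.52 ± 0.38). Of 19 mesenchymal markers, 5 rose and 7 fell (5 and 8 adjusted over the list alone, median -0.13, camera adjusted p = 0.192). In S1a alone, 3 rose and 9 fell (4 and 10 adjusted over the list alone), and the list passed as lower (camera adjusted p = 0.0345, adjusted p = 0.428 with an estimated correlation). The list did not pass in S1b (camera adjusted p = 0.4) or between S1b and S1a (camera adjusted p = 0.325), so the isolates were not shown to differ in it. S100A4, a calcium-binding protein linked to motility, fell by 3.54 ± 0.072 on the log2 scale, from 20700 ± 795 units to 2530 ± 30.8 in S1a and 1240 ± 71.5 in S1b. The cadherin CDH11 fell by 2.46 ± 0.1, the collagen COL5A1 by 2 ± 0.15 and the transcription factor SNAI2 by 1.24 ± 0.089. The epithelial and luminal calls ended with shared-probe suffixes left out (adjusted p = 0.3 and 0.31), the epithelial call also with no filter and the luminal call with a filter at the 60th percentile.

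Secreted proteases and their inhibitors changed in both directions. Of 22 extracellular proteases, 5 rose and 9 fell (5 and 9 adjusted over the list alone, camera adjusted p = 0.181); the median was -0.41 with camera's direction down, while the mean was 0.06 with fry's direction up. MMP1 and ADAMTS1 rose, while cathepsin L (CTSL) fell by 1.26 ± 0.09 and the urokinase gene PLAU by 1.08 ± 0.078 on the log2 scale. Of 13 protease inhibitors, 2 rose and 7 fell (2 and 8 adjusted over the list alone, median -0.42, camera adjusted p = 0.146). SERPINE2 rose by 1.76 ± 0.085, and TIMP1, TFPI2 and the cystatin CST3 fell by 1.14 ± 0.089, 1.49 ± 0.12 and 0.74 ± 0.07. Of 38 matrix genes, 13 rose and 11 fell, also adjusted over the list alone (median 0.03, mean -0.03, camera adjusted p = 0.654); the glycoprotein EFEMP1 fell by 2.48 ± 0.089 and CCN2, SRGN and COL13A1 rose.

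Inflammatory genes were also mixed. Of the 4 chemokines tested, CXCL1, CXCL8 and CXCL3 (0.87 ± 0.26, adjusted p = 0.0199) passed and CXCL2 did not (0.53 ± 0.34, adjusted p = 0.225), also adjusted over the list alone. The CXCL3 call ended without parental replicate 2 (adjusted p = 0.078), S1a replicate 2 (0.0582) or S1b replicate 1 (0.0587) and with no filter (0.0546). Of 26 cytokines and growth factors, 7 rose and 10 fell (8 and 11 adjusted over the list alone, median -0.34, camera adjusted p = 0.478): the inflammatory cytokine IL1B rose by 2.11 ± 0.15, while the epidermal growth factor receptor ligand TGFA fell by 2.41 ± 0.17 and the angiogenic factor VEGFA by 1.57 ± 0.078. Of 23 NF-kappa B responsive genes, 5 rose and 9 fell, also adjusted over the list alone (median -0.34, mean 0.11, camera adjusted p = 0.648), with BCL2A1, CXCL1, CXCL8 and IL1B leading by p-value. Of 18 cytokine receptors and signal proteins, 3 rose and 7 fell, also adjusted over the list alone (median -0.19, mean 0.06, camera adjusted p = 0.731). Beside IL13RA2, the transcription factor STAT3 rose by 0.69 ± 0.072, IL1R1, the interleukin 1 receptor, fell at least 5.11-fold, and IL13RA1 fell by 0.87 ± 0.12.

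Proliferation genes were slightly higher on balance and ribosomal protein genes slightly lower. Of 55 proliferation genes, 25 rose and 5 fell, also adjusted over the list alone (median 0.19, camera adjusted p = 0.0183, adjusted p = 0.236 with an estimated correlation), led by TK1 (0.9 ± 0.082), PLK1 (0.87 ± 0.094), NDC80 (0.64 ± 0.072) and CDT1 (1.06 ± 0.13). Of 36 ribosomal protein genes, none rose and 17 fell, also adjusted over the list alone (median -0.25, camera adjusted p = 0.000898, adjusted p = 0.74 with an estimated correlation). This direction turned under quantile normalization (camera adjusted p = 0.911), and the call also ended with shared-probe suffixes left out. RPS4X, RPS19, RPS18 and RPL34 led with changes of -0.54 ± 0.096, -0.53 ± 0.096, -0.58 ± 0.11 and -0.49 ± 0.098. The RPS19 call ended under quantile normalization (-0.05, adjusted p = 0.403) and the RPL34 call with median centring (-0.3, 0.0627). Under quantile normalization RPS4X, RPS18 and RPL34 kept their calls at -0.14, -0.19 and -0.24. Of 46 actin and motility genes, 9 rose and 14 fell (10 and 14 adjusted over the list alone, median -0.1, camera adjusted p = 0.318); caldesmon (CALD1) fell by 1.15 ± 0.085, and the myosin genes MYL9 (-1.11 ± 0.084) and MYH10 (-1.43 ± 0.12) and gelsolin (GSN, -1.55 ± 0.13) fell as well. Of 12 integrin subunits, 1 rose and 4 fell, also adjusted over the list alone (median -0.07, mean 0.06, camera adjusted p = 0.542): ITGB2, the beta subunit of leukocyte integrins, rose by 3.58 ± 0.14 from 47.2 to 605 units, and ITGAV, ITGB5 and ITGA6 fell by 0.99 ± 0.082, 1.1 ± 0.098 and 0.76 ± 0.089 (the ITGB5 call ended with shared-probe suffixes left out, adjusted p = 0.0548). The proliferation call ended with a filter at the 60th percentile, under quantile or cyclic loess normalization and with shared-probe suffixes left out (highest adjusted p = 0.126).

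**Figure D3:**
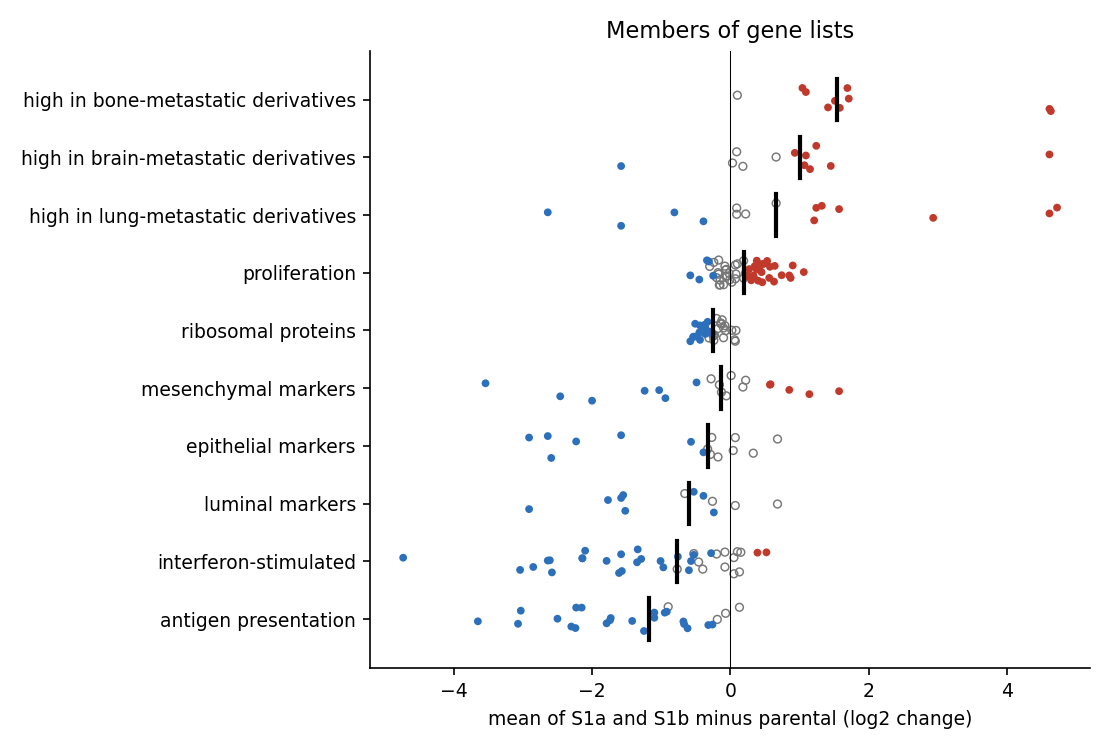
Log2 change in the mean of S1a and S1b against parental (horizontal axis) for the tested members of 10 gene lists; points are genes, filled red or blue if they rose or fell past the threshold and open if not, and black bars are list medians. The medians run from 1.54 for bone-metastatic derivatives to -1.18 for antigen presentation, and the ribosomal direction turned under quantile normalization.

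In all, 8 of 31 lists passed with camera, 3 up and 5 down. With an estimated correlation, tested on 3 degrees of freedom, 0 passed, and fry gave 20. The 8 are those of bone- and brain-metastatic derivatives and proliferation (up) and of antigen presentation, interferon, epithelial, luminal and ribosomal protein genes (down). The estimated correlation was above the preset 0.01 for ribosomal protein (0.846), luminal (0.163), antigen presentation (0.148), epithelial (0.0985) and bone (0.0472) genes. It was below the preset for brain, proliferation and interferon genes. Where it was above, the camera p-value at the preset may be too small. fry asks whether the genes of a list move one way on balance and does not compare them with other genes.

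Each isolate on its own differed from the parental line in a similar number of genes. In S1a, 3057 genes passed with limma (1510 higher, 1547 lower), and 662 of them changed at least 2-fold. In S1b, 3244 passed (1616 higher, 1628 lower), 767 of them at least 2-fold. With median centring, 72.9% of the S1a calls and 71.2% of the S1b calls were higher, so this balance rests on the deposited scaling. MMP1, CXCL1, BCL2A1 and IL1B were higher and HLA-B, IFIT1, S100A4 and TNFSF10 lower in both. With camera, 8 lists passed in S1a (2 up, 6 down) and 9 in S1b (4 up, 5 down), and 0 in either with an estimated correlation. Beside 7 of the 8 lists of the mean, S1a had the mesenchymal markers and lacked proliferation. Beside all 8, S1b had oxidative phosphorylation, where 13 genes rose and 2 fell, also adjusted over the list alone (median 0.14, camera adjusted p = 0.0381, adjusted p = 0.606 with an estimated correlation). In S1a 11 of these rose and 5 fell, also adjusted over the list alone (median 0.14, camera adjusted p = 0.129). Between S1b and S1a none passed (camera adjusted p = 0.171), so the isolates were not shown to differ in this list. The estimated correlation of the oxidative phosphorylation list was 0.279, above the preset 0.01. Without S1a replicate 1 or S1a replicate 2, the S1a count was 1977 or 1902.

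The isolates shared most of their changes. In the same direction, 2437 genes passed in both, 1218 higher and 1219 lower, and 6 passed in opposite directions. Independent lists would share 636 (313 higher and 323 lower). Unchanged groups simulated with shared simulated parental arrays shared 0.02 on average, a count near 0 by construction because they hold no effect. Across genes, the log2 changes of S1a and S1b had r = 0.896 against 0.499 in the simulation. Their covariance was 0.476 against 0.0267, a difference of 0.449. The simulation gave all groups the same spread. The parental arrays differed more from each other (median absolute log2 difference 0.18) than those of S1a (0.121) or S1b (0.145). Shared parental arrays may thus add more than simulated. With S1a set against parental replicate 1 and S1b against parental replicate 2, a setting chosen after the data were seen, the covariance was 0.427 (r = 0.736), and with these arrays exchanged it was 0.435 (r = 0.76). In these settings 1931 and 1965 genes passed in both in the same direction, where independent lists would share 576 and 568, and 29 and 15 in opposite directions. These settings ended the sharing and also left each isolate a single parental array, so the lower counts cannot be put down to either. Part of the excess over independent lists with both arrays may still come from the shared parental arrays. Of 1415 genes that passed in one isolate and not the other, 85 also passed between S1b and S1a, so most of these were not shown to differ.

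Of the genes named between S1b and S1a, FGF13, ENG and SPARC differed most toward S1b and IL13RA2 most toward S1a. FGF13, a growth factor homologue that acts inside the cell, was at 862 ± 68.1 units in S1b (SD, n = 2) and at 11 ± 11.6 in S1a, at least 19.6-fold higher in S1b (limma adjusted p = 0.00696). The co-receptor endoglin (ENG) was higher in S1b by 3.32 ± 0.3 (log2, SE, adjusted p = 0.000692), and the matricellular gene SPARC was at least 8.65-fold higher (380 against 37 units, adjusted p = 0.000686). MMP1 was higher in S1b by 0.88 ± 0.089 (adjusted p = 0.00125). In the other direction, IL13RA2 was lower in S1b by -3.51 ± 0.35 (75 against 892 units, adjusted p = 0.00123), CST7, a cystatin, at least 4.4-fold, the adhesion molecule ICAM1 at least 2.04-fold and the cholesterol exporter ABCA1 at least 3.35-fold. The cancer-testis gene SSX1 was lower by -3.05 ± 0.37 (57.3 against 502 units), though its probe set shares probes with related SSX genes. The ICAM1 difference shrank from -2.73 to -1.78 without S1b replicate 1 and to -1.44 with the mean of its probe sets (limma adjusted p = 0.0684), each without a call. Without parental replicate 1 it was -0.72, also without a call. That value came from another ICAM1 probe set, which then had the highest mean, since this comparison holds no parental array.

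Further genes higher in S1b were LYPD1 (1.39 ± 0.3), the sialyltransferase ST3GAL1 (1.17 ± 0.24), the collagen COL6A3 (1.12 ± 0.19), the inositol transporter SLC5A3 (0.92 ± 0.11), the adiponectin receptor ADIPOR2 (0.89 ± 0.11) and the phosphatase PTP4A1 (0.82 ± 0.13). Further genes lower in S1b were the small GTPase RRAD (at least 2.01-fold), CEMIP (at least 1.9-fold), the desaturase SCD5 (-1.47 ± 0.28), STOML1 (-1.46 ± 0.17) and stomatin (STOM, -1.44 ± 0.12). The RRAD difference went from -2.89 to -0.75 with shared-probe suffixes left out (adjusted p = 0.6) and to -1.82 with the mean of its probe sets (0.0679), and that of PTP4A1 to 0.29 with the mean of its probe sets (0.272), each without a call. Of the other genes followed up in published work, CXCL8 was lower in S1b by -0.46 ± 0.097 (adjusted p = 0.0472), and CXCL1 (0.42 ± 0.14, adjusted p = 0.194), IL6 (-0.86 ± 0.34, adjusted p = 0.256) and FSCN1 (-0.51 ± 0.35, adjusted p = 0.563) did not pass. The CXCL8 call ended without the variance trend (limma adjusted p = 0.213), with no filter (0.0735) and with the mean of its probe sets (0.138). It also ended with median centring (0.0646), quantile normalization (0.0632) and a replicate block (0.0964). With an S1a or S1b array left out, its difference ran from -0.55 to -0.37. CXCL1 passed with only the S1a and S1b arrays in the fit (limma adjusted p = 0.0402). In FSCN1 the dimmer probe set disagreed in sign.

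**Figure D4:**
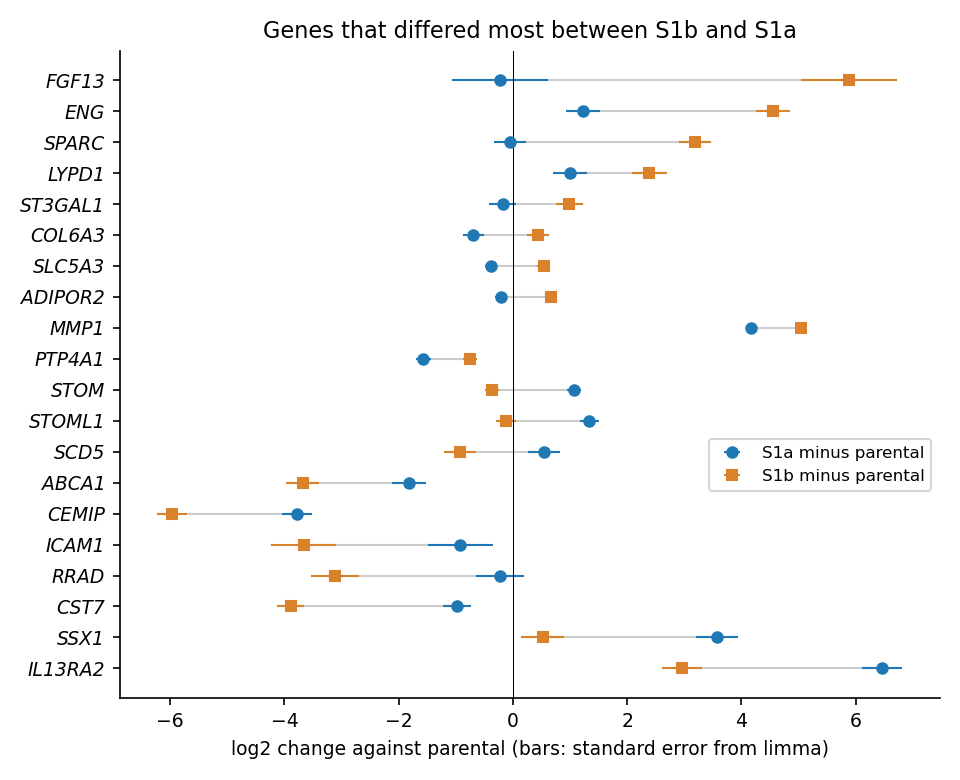
Log2 change against parental (horizontal axis) in S1a (circles) and S1b (squares) for the 20 named genes with the largest differences between the isolates; bars are standard errors from limma. FGF13 and SPARC rose in S1b with S1a near 0, and IL13RA2 rose in both but more in S1a.

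The spread used between the isolates was also estimated from the parental arrays. These differed more from each other (median absolute log2 difference 0.18) than those of S1a (0.121) or S1b (0.145). With only the S1a and S1b arrays in the fit, 330 genes passed. In the main fit, 147 of 7791 genes (1.89%) passed between the isolates, 36 higher and 111 lower in S1b, and 32 of them differed at least 2-fold. This count moved more than any other with the array left out: 347 without either parental replicate, 34 and 36 without S1a replicate 1 and 2, and 46 and 22 without S1b replicate 1 and 2. Of the 20 genes named by size, 7 kept their call with each array left out, namely CST7, ENG, SPARC, CEMIP, IL13RA2, MMP1 and STOM, and 4 kept it without the variance trend, which left 4 calls in all. FGF13 lost its call without S1b replicate 1 (adjusted p = 0.107) or S1b replicate 2 (0.118). Of all 43 genes named and called in this comparison, 9 kept the call with each array left out, the 7 above and SCD and TIMP3.

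By group, the lists of lipid synthesis, protease inhibitor and antigen presentation genes passed as lower in S1b with camera, with few single genes past the threshold. Of 23 cholesterol and fatty acid genes, none rose and 2 fell (0 and 5 adjusted over the list alone, median -0.22, camera adjusted p = 0.00191, adjusted p = 0.219 with an estimated correlation), the desaturase SCD by 1.05 ± 0.095 and the lipid synthesis regulator SREBF1 by 1.2 ± 0.21 on the log2 scale. Of 13 protease inhibitors, 3 fell (1 rose and 4 fell adjusted over the list alone, median -0.22, camera adjusted p = 0.00191, adjusted p = 0.219 with an estimated correlation), namely TIMP3 (-1.31 ± 0.11), CST3 (-0.67 ± 0.081) and SERPINB1 (-0.52 ± 0.11). Of 26 antigen presentation genes, 4 fell (1 rose and 7 fell adjusted over the list alone, median -0.16, camera adjusted p = 0.00191, adjusted p = 0.423 with an estimated correlation): the immunoproteasome genes PSMB9 (-0.82 ± 0.11), PSMB10 (-0.7 ± 0.1) and PSMB8 (-0.55 ± 0.12), and CD74 (-0.52 ± 0.1). The CD74 call ended without the variance trend (limma adjusted p = 0.204), with no filter (0.0611) and with the mean of its probe sets (0.0571). It also ended under quantile normalization (0.0621) and with a replicate block (0.0828). Of 37 interferon-stimulated genes, 1 fell, also adjusted over the list alone (ISG15, -0.57 ± 0.088; median -0.2, camera adjusted p = 0.00191, adjusted p = 0.219 with an estimated correlation).

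Of 23 NF-kappa B responsive genes, 4 fell in S1b (1 rose and 6 fell adjusted over the list alone, median -0.31, camera adjusted p = 0.00478, adjusted p = 0.219 with an estimated correlation): IL1B (-1.19 ± 0.17), ICAM1, TNIP1 (-0.46 ± 0.088) and CXCL8. Of 26 cytokines and growth factors, 3 fell (6 adjusted over the list alone, median -0.3, camera adjusted p = 0.00571, adjusted p = 0.329 with an estimated correlation), IL1B, IL11 (-0.75 ± 0.12) and the macrophage growth factor CSF1 (-1.23 ± 0.24). The CSF1 call ended without the variance trend (limma adjusted p = 0.213), with the mean of its probe sets (0.123), with no filter (0.0821) and with a replicate block (0.0666). Of 28 genes of the unfolded protein and amino acid response, 3 fell (1 rose and 3 fell adjusted over the list alone, median -0.12, camera adjusted p = 0.00698, adjusted p = 0.309 with an estimated correlation), the cystine transporter SLC7A11 (-0.63 ± 0.079), TRIB3 (-0.72 ± 0.11) and SLC3A2 (-0.42 ± 0.088). Of 15 epithelial markers, 1 fell (3 adjusted over the list alone, median -0.27, camera adjusted p = 0.00797, adjusted p = 0.388 with an estimated correlation), KRT8 (-0.46 ± 0.1). Of 55 proliferation genes, 2 rose and 2 fell (11 and 2 adjusted over the list alone, median 0.13, camera adjusted p = 0.00883, adjusted p = 0.219 with an estimated correlation): KIF20A (0.6 ± 0.12) and KIF2C (0.49 ± 0.091) rose, and CDC45 (-0.54 ± 0.11) and PCNA (-0.47 ± 0.093) fell. The CDC45 call ended without the variance trend (limma adjusted p = 0.213), with the mean of its probe sets (0.0635) and with no filter (0.0666). It also ended under quantile normalization (0.0632) and with a replicate block (0.0828). None of the 36 ribosomal protein genes passed, also adjusted over the list alone (median 0.13, camera adjusted p = 0.00191, adjusted p = 0.619 with an estimated correlation), and their direction turned under quantile normalization. Their estimated correlation was 0.846, so the camera p-value at the preset 0.01 is likely too small.

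These are the 10 lists that passed between the isolates, 2 up and 8 down, while 0 passed with an estimated correlation and fry gave 6. With shared-probe suffixes left out, none of the 10 passed. The epithelial call also ended with no filter and without S1b replicate 2. The cytokine call with the mean of a gene's probe sets and the ribosomal call under quantile or cyclic loess normalization and without S1a replicate 1 or S1b replicate 1.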

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

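The comparison of S1b with S1a was planned, and no test in this part was chosen after the result was seen. It is also the test of whether the changes of the isolates against the parental line differ, and 147 genes differed by it. Among these, FGF13 differed by 6.11 (S1b minus S1a, log2), ENG by 3.32, SPARC by 3.23, LYPD1 by 1.39, ST3GAL1 by 1.17, COL6A3 by 1.12, SLC5A3 by 0.92, ADIPOR2 by 0.89, MMP1 by 0.88 and PTP4A1 by 0.82. In the other direction, IL13RA2 differed by -3.51, SSX1 by -3.05, CST7 by -2.91, RRAD by -2.89, ICAM1 by -2.73, CEMIP by -2.19, ABCA1 by -1.85, SCD5 by -1.47, STOML1 by -1.46 and STOM by -1.44. The values of FGF13, SPARC, CST7, RRAD, ICAM1, CEMIP and ABCA1 depend on the pseudocount, since their dimmer side lay below 44 signal units.

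Of the 147 genes, 95 were also called in the mean of both isolates against parental, and 83 had the same sign in both isolates. MMP1, for example, rose by 4.17 in S1a and by 5.05 in S1b. The calls of CST7, ENG and SPARC held under every alternative that gave them a value. No explanation was weighed for these genes.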

How the results depend on the processing

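The separate parental arrays for S1a and S1b were chosen after the data were seen, and every other setting before. Of 191 named gene values, alternatives gave 3705 further values: 3413 kept direction and side of the threshold, 253 lost it, 28 gained it and 11 changed sign. Of 167 called values, 112 stayed called under every alternative that kept all arrays. Of the 3600 calls in the mean of both isolates, 2858 were kept with median centring, 3274 with quantile and 3327 with cyclic loess normalization. Median centring moved the median change of all genes from -0.026 to 0.165 and the share of higher calls from 49.2% to 71.3%, so which small changes pass rests on the deposited scaling. Of the 3600 directions, 3600 were kept with median centring, 3597 with quantile and 3600 with cyclic loess normalization. Signal over background limits the dim genes, and background correction was not varied here because scanner files were not used. With 1 array of a group left out, the lone array is assumed to vary like the other groups. The probe set of each gene was then chosen again, so a value could move to another probe set. Except where stated, the cause was not tested.

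S1b against S1a was least stable: 147 calls became 63 with no filter, 4 without the variance trend, 320 with array weights, 60 with the mean of a gene's probe sets, 58 with shared-probe suffixes left out (fewer genes tested), 32 with a 2-fold change required, 330 with only the compared arrays, and 22 to 347 with an array left out. Against parental, all probe sets gave 4654 (S1a), 4947 (S1b) and 5598 (mean), since more features were tested. Suffixes left out gave 1728, 1889 and 2056, and a 2-fold change 662, 767 and 714. Leaving out an array gave 1902 to 2912 for S1a. Genes called in both isolates numbered 1408 with suffixes left out and 504 with a 2-fold change.

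The covariance of 0.476 became 0.535 with no pseudocount, 0.383 with the 25th percentile, 0.491 with no filter, 0.373 with the 60th percentile, 0.462 with loess, 0.43 with all probe sets, 0.437 with their mean, 0.5 with suffixes left out, 0.477 to 0.505 with an array left out, and 0.427 and 0.435 with separate parental arrays. Of 8 lists called, 4 remained in number with suffixes left out, 0 with an estimated correlation and 20 with fry.

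Signs changed for COL1A1 (0.25) and H2AX (-0.12) with the mean of probe sets, COL6A3 (0.07) with median centring, and EGFR (-0.04) and TPI1 (-0.27) with suffixes left out. With an array left out, COL6A3 ranged from -0.39 to 0.14, CORO1A from -0.06 to 1.09, CXCL2 from -0.19 to 1.25, KDR from -0.42 to 1.31, and FSCN1 (S1b minus S1a) from -0.88 to 0.26, where its other probe set had the higher mean without parental replicate 2 or S1a replicate 2.

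The replicate numbers did not pair the arrays (correlations of replicate differences -0.005, -0.067 and -0.058). With the replicate number as a block, the counts were 3350 for the mean of both isolates and 64 for S1b against S1a.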

Other observations

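The tests of spike-in signals, of leukocyte markers and of the antigen presentation genes within the major histocompatibility complex were chosen after the result was seen, as were the values by chromosome and by window of genes. Oxygen-related genes moved both ways in the mean of both isolates against parental. Of 28 hypoxia genes, 7 rose and 14 fell, also adjusted over the list alone (median -0.26, camera adjusted p = 0.318): the vasodilator peptide gene ADM rose by 2.12 ± 0.096 (log2, SE) and the mitophagy receptor BNIP3L by 1.13 ± 0.098, while VEGFA fell by 1.57 ± 0.078 and the prolyl hydroxylase P4HA2 by 1.76 ± 0.12. Of 22 angiogenesis genes, 6 rose and 9 fell, also adjusted over the list alone (median -0.15, mean 0.07, camera adjusted p = 0.882), and EPAS1, a hypoxia-inducible factor, fell by 1.32 ± 0.088. Of 25 TGF-beta targets, 4 rose and 10 fell, also adjusted over the list alone (median -0.25, camera adjusted p = 0.201), with IL11 up by 1.04 ± 0.11 and TGFBI down (-1.03 ± 0.089).

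Among stress and growth responses, the phosphatases DUSP1 (1.71 ± 0.094), DUSP4 (1.23 ± 0.077) and DUSP5 (0.92 ± 0.086) and IER2 (0.93 ± 0.082) rose, and of 21 immediate early genes 7 rose and 3 fell (9 and 3 adjusted over the list alone, median 0.09, camera adjusted p = 0.134). Of 19 p53 targets, 9 rose and 1 fell, also adjusted over the list alone (median 0.31, camera adjusted p = 0.134), with ZMAT3 (0.74 ± 0.17, 0.48 without parental replicate 2), TP53I3 (0.57 ± 0.12), CCNG1 (0.4 ± 0.074) and TNFRSF10B (0.53 ± 0.069) rising, the last without a call under the mean of its probe sets (limma adjusted p = 0.617). Of 28 unfolded protein and amino acid response genes, 9 rose and 8 fell (9 and 9 adjusted over the list alone, median -0.12, mean 0.06, camera adjusted p = 0.882), with ATF4 (0.92 ± 0.082), PPP1R15A (0.91 ± 0.084) and ASNS (0.72 ± 0.076) up and PDIA4 (-0.97 ± 0.083) down. Of 26 apoptosis regulators, 6 rose and 7 fell, also adjusted over the list alone (median 0.05, camera adjusted p = 0.882), including falls of CASP6 (-1.43 ± 0.11) and CFLAR (-1.08 ± 0.084).

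Metabolic lists did not pass in the mean of both isolates. Of 32 oxidative phosphorylation genes, 13 rose and 3 fell (14 and 4 adjusted over the list alone, median 0.08, camera adjusted p = 0.0732; in S1b alone camera adjusted p = 0.0381, adjusted p = 0.606 with an estimated correlation), led by UQCRC2 (0.72 ± 0.069), NDUFB8 (0.58 ± 0.084, no call under the mean of its probe sets, limma adjusted p = 0.0666), NDUFS1 (0.57 ± 0.081) and NDUFV2 (0.47 ± 0.072). Of 19 glycolysis genes, 6 rose and 6 fell, also adjusted over the list alone (median -0.07, mean 0.01, camera adjusted p = 0.882): HK2 was at 0.62 ± 0.1 and PGK1 at -0.51 ± 0.07 (-0.32 with median centring). SLC2A1 was at -0.73 ± 0.12 and TPI1 at 0.4 ± 0.07, and both lost the call with shared-probe suffixes left out (limma adjusted p = 0.105 and 0.428), TPI1 also under the mean of its probe sets (0.269). Of 23 cholesterol and fatty acid genes, 3 rose and 5 fell, also adjusted over the list alone (median 0.01, camera adjusted p = 0.882), with EBP at -1.29 ± 0.088, ACAT2 at 0.76 ± 0.094, SC5D at -0.89 ± 0.11 (no call under the mean of its probe sets, limma adjusted p = 0.0651) and MVD at least 2.84-fold higher. Of 10 histone genes, 2 rose and 3 fell, also adjusted over the list alone (median -0.07, camera adjusted p = 0.809): H1-10 was at 0.74 ± 0.14, H2BC5 at -0.74 ± 0.092 (-0.42 with the mean of its probe sets), H2BC12 at -0.47 ± 0.068 (-0.28 with median centring) and H2AX at 0.41 ± 0.082, whose sign turned under the mean of its probe sets.

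Of 6 basal breast markers, 2 rose and 2 fell (2 and 3 adjusted over the list alone, median -0.15, camera adjusted p = 0.882). LAMB3 rose by 0.57 ± 0.08, EGFR was at 0.81 ± 0.084 with its sign turned when shared-probe suffixes were left out and its call lost under the mean of its probe sets (limma adjusted p = 0.126). CAV1 was at -0.3 ± 0.076, with its call lost under median centring (-0.11, limma adjusted p = 0.416) and without S1a replicate 1 (0.0624). Of markers of other cell types, 5 leukocyte genes were tested, of which LAPTM5 rose by 0.91 ± 0.079 and CD14 was at -1.08 ± 0.37 (1 and 1 adjusted over the list alone, median -0.53, mean -0.17, camera adjusted p = 0.882, direction up). The CD14 call ended without parental replicate 2 (limma adjusted p = 0.206), S1a replicate 1 (0.0998), S1b replicate 1 (0.0571) or S1b replicate 2 (0.0582), with median centring (0.0708), quantile (0.0971) or cyclic loess normalization (0.0969), with no filter (0.0757), with array weights (0.0629) and with the isolates taken as 1 group (0.0745). CORO1A (0.51 ± 0.43) and HCLS1 (-0.67 ± 0.46) did not pass. The dimmer side lay below 44 units for CD14 (41.5, isolates), CORO1A (37.1, parental) and HCLS1 (38.4, isolates). The fitted changes of these leukocyte genes thus depend on the pseudocount. Of 3 fibroblast genes, COL1A2 was past the threshold (-1.32 ± 0.38, also adjusted over the list alone). Its mean signal in the isolates lay below 44 units, so this change depends on the pseudocount. COL1A2 did not pass without parental replicate 2 or under quantile (limma adjusted p = 0.0505) or cyclic loess normalization (0.0508). COL1A1 (-0.32 ± 0.21) and COL6A3 (-0.13 ± 0.16) did not pass. Of 3 endothelial genes, ENG rose at least 6.3-fold in the mean of both isolates, from 17.8 units to 47.2 in S1a and 507 in S1b, so mostly in S1b, and ROBO4 rose by 1.15 ± 0.26, also adjusted over the list alone, and KDR did not pass (0.45 ± 0.47). No erythroid gene was tested (0 of 10 on the list).

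The number of genes called in the mean of both isolates was 3600. Leftover intensity-dependent differences between arrays were argued against as its source, since quantile and cyclic loess normalization gave 3602 and 3571. Separate labelling of parental and isolate RNA could not be excluded: spike-in signals were 0.51 higher on isolate arrays, beside a difference of 0.8 between the parental arrays. A difference between the isolated and parental populations stays open as well.

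Antigen presentation and interferon-stimulated genes fell in both isolates. The linear scaling was argued against, since the highest camera adjusted p of both lists under quantile and cyclic loess normalization was 1.19e-06. Leukocytes in the parental cultures were argued against as the main source of the signal that the isolates lack. That share was 82.5% for HLA-B, yet of 18 fixed leukocyte markers only 1 had a parental signal of 2 times the filter level of 44 or more, LAPTM5, which rose, and PTPRC, CORO1A, LYZ and TYROBP lay at 30.1, 37.1, 22.1 and 14.6. A lesser contribution of leukocytes was not excluded. Of 7 markers above the filter level, 0 fell past the threshold without a filter, but 6 were lower and close to that level. CD14 passed with the filter (limma adjusted p = 0.0356), and CD163, below that level, without it (0.00475). The class II genes CD74 (-1.42), HLA-DRA (-3.03), HLA-DRB1 (-3.07) and HLA-DPA1 (-3.65), which leukocytes also express, fell. HLA-DPA1 lay at 36 units in the isolates, below 44, so its value depends on the pseudocount. Loss of the chromosome segment that holds the major histocompatibility complex may contribute. The median change of its 42 other genes was -0.37 (95% bootstrap interval -0.45 to -0.12), beside -0.21 for all genes of chromosome 6. As the whole cause it was argued against: its 15 antigen presentation genes had a median of -2.15, with a difference of medians of -1.79 (-2.13 to -1.26). The 11 antigen presentation genes elsewhere had a median of -0.62. These intervals treat genes as independent, though neighbouring genes changed together and HLA probe sets share probes, so they may be too narrow. Lower interferon activity in the isolates stays open and was not tested.

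Neighbouring genes changed together in the mean of both isolates, with a rank correlation across genes of 0.212 (95% of 100000 permuted orders up to 0.0222), where genes are not independent replicates. Shared probes of neighbouring paralogs were argued against (0.184 without such pairs and probe sets, permuted up to 0.0308), as was bias by gene density, length or signal (0.147 for genes 10 places apart after a fit on these, permuted up to 0.0223). Long segments with another copy number in the isolates are a candidate explanation: genes 10 places apart had 0.137 (permuted up to 0.0224, p = 1e-05, the smallest the permutations can give), and 0.0313 in S1b minus S1a (permuted up to 0.0223, p = 0.00304). DNA copy number was not analysed here.

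By chromosome (gene order from GRCh38.p14), genes of X were lowest, with 169 of 267 falling and 19 rising and a median of -0.54 (-0.53 in S1a and -0.51 in S1b). Among windows of 41 genes, the lowest ran from PLCXD1 to PDHA1 on X (median -0.8) and the highest from NPIPB15 to SLC7A5 on chromosome 16 (0.72), where 1000 permuted orders had a largest size of 0.42 at their 95th percentile. Between S1b and S1a, the window from MAVS to PYGB on chromosome 20 had a median of -0.44 (permuted 0.19), with 90.2% of its genes below 0. These windows were chosen after their values were seen.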
